A study of Mus musculus with 24 samples.

How the data were processed

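The authors deposited per-cell tables for the CITE-seq libraries and fragment files for the multiome ATAC libraries; these were analysed, and groups were taken from the sample labels. The CITE-seq tables hold, for each cell, a condition, the authors' cell type label, a YFP count, the percent of mitochondrial counts, a doublet score and, for macrophages, 3 scores of gene modules, all as deposited by the authors. Filters, annotation and score methods are not recorded with the tables, nor whether the YFP count comes from a transcript or a tag. The percent of mitochondrial counts in the deposited tables stops at 40. Cell Ranger, Bowtie2 and mm10 are named in the submitters' processing notes. The tables hold no total RNA counts, genes per cell or antibody values, so alternatives that need them were not run. The table of all cells had 17294 cells in 23 labels and the macrophage table held 13688 cells in 13 labels, all of them also in the first table. Each deposited ATAC file lists unique fragments with a count of read pairs, made with cellranger-arc 2.0.2 against mm10, per the file headers (106604394 and 107619741 read pairs).

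Shares of cells and of cells with 1 or more YFP counts were given exact (Clopper-Pearson) intervals at 95%; where a share is 0, the limit is 3 counts of the total. Scores were summarised by medians and SDs over cells.

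Nuclei were kept at 2000 or more fragments and a TSS enrichment of 4 or more. The reference annotation (GRCm38, the assembly named mm10) gives no strand, so the promoter end of a protein-coding gene was taken as the gene end with at least 3 times as many insertions as the other (11901 of 21883 genes), and gene windows extend 2000 bp beyond both ends instead of upstream only. For genes without a clear promoter end, promoter windows were summed over both gene ends, or lay at the start coordinate in genes of 2000 bp or less. Both libraries were clustered together on 5000 bp bins by latent semantic indexing (30 components) with 20 neighbours and the Leiden method at resolution 1. Doublets were scored as the share of simulated doublets among neighbours, and nuclei at 0.6 or more were left out.

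Clusters were named from fixed markers: at least 3 markers of a class with a log2 fold of 1 or more over other nuclei, and more of them than of any other class. Hepatocyte clusters were named in a second step, against the clusters named in the first, because hepatocytes make up most nuclei. The naming rule and the doublet limit were set after the data were seen; lists, markers, main comparisons and the rule for named genes were set before the data were examined. Clusters whose median doublet score was 0.6 or more, or whose 10 leading genes held more markers of another class, stayed unnamed (4.52% of control and 5.43% of 8-week nuclei).

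Fragments were summed per class and library, and scaled per 1000000 fragments of the class with a pseudocount of 1 for log2 ratios. Genes with 50 or more fragments in all were compared. Ratios of sums carry exact conditional 95% intervals, which compare these libraries and not the conditions. The median of each fixed gene list was placed among 10000 random lists of equal size matched on count. Percentiles of 97.5 and above or 2.5 and below were taken as apart. Random lists were drawn without regard to position. Members of a fixed list that lie side by side can share fragments and are then not independent. Percentiles and counts of members can therefore overstate how far a list stands apart. The fixed lists were Kupffer cell identity, monocyte and recruited macrophage, lipid-associated macrophage, MHC class II, MHC class I and antigen processing, interferon-gamma response, type I interferon response, inflammatory cytokines and NF-kB, scavenger and phagocytic receptors, iron handling, lipid handling, endothelial-like Kupffer cell genes, hepatocyte acute phase, sinusoidal endothelial and stellate cell activation. Lists with fewer than 3 measured members were left out.

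Named genes were the 10 highest and 10 lowest in Kupffer cell-like nuclei (5 and 5 in endothelial-like and hepatocyte-like nuclei and among windows), ranked by the interval bound nearest to 1, and up to 4 members of each list whose nearest bound lay farthest from 1. The fixed rule asked for list members in Kupffer cell-like nuclei only; list members in endothelial-like and hepatocyte-like nuclei, from 8 of the lists, were added to it, and not every member is printed. Some genes picked by these rules are not reported here. The sums over the Hoxb cluster were chosen after the values of its genes were seen. The method was tested on simulated counts for 12756 genes in Kupffer cell-like nuclei with 200 changed genes: at a fold of 1.5, 61.0% of changed genes had an interval off 1 against 4.17% of unchanged genes, at a fold of 2 94.5%, and at a fold of 3 99.5%, and none had the wrong direction. The simulated counts varied by counting error alone, as the intervals assume. They therefore cannot show how often differences between mice or libraries move an interval off 1.

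Alternatives were fragment minimums of 1000 and 5000 (applied to the classes without new clusters), a TSS enrichment minimum of 6, Leiden resolutions of 0.5 and 2, doublets kept, promoter windows of 1000 bp either side, scaling to promoter fragments or to the median ratio, thinning to 2000 fragments per nucleus, a pseudocount of 5, a count minimum of 20, windows of 1000 bp, and 40 fragments per 1000000. The planned motif comparison was not run because no genome sequence was used here. Python 3.11.15 was used with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, leidenalg 0.10.2, igraph 0.11.9 and matplotlib 3.10.9.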

Results

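The series holds 24 mouse samples on the liver during and after infection with Trypanosoma brucei brucei, a blood parasite that can be cured with the drug melarsoprol. CITE-seq, which reads RNA and antibody tags in the same cells, was done with 158 antibodies on sorted liver macrophages in 4 conditions with 1 library each: control, infected at day 28, and 2 and 8 weeks post curing. The control mice were given melarsoprol 8 weeks before collection. The mice were Flt3-Cre Rosa26-Yfp animals, in which descendants of Flt3-expressing haematopoietic progenitors carry the fluorescent protein YFP. Multiome ATAC-seq of whole-liver nuclei, which maps open chromatin, was done in control and at 8 weeks post curing with 1 library each. The cell tables held 3491 control, 5545 infected, 3110 2-week and 5148 8-week cells. The ATAC files held 71388612 and 68178032 unique fragments. No condition analysed here had a replicate, so intervals on shares and ratios are 95% intervals for counting error only. The 12 bulk ATAC libraries (5 control, 3 at 2 weeks and 4 at 8 weeks) and the multiome RNA were not analysed here.

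The first comparison asks which cells made up the sorted macrophage fraction during infection and after cure. Cells that the authors labelled Kupffer cells (KC), the resident macrophages of the liver sinusoids, were 64.1% of control cells (62.4 to 65.6). In the infected library 0 of 5545 cells carried that label, which allows a share of up to 0.0541%. The label was back at 74.7% (73.1 to 76.2) at 2 weeks and 65.6% (64.3 to 66.9) at 8 weeks post curing. Cells labelled Mac took their place at day 28, at 78.5% against 0.315% in control, 0.0965% at 2 weeks and 0.0777% at 8 weeks. Of the cells in the macrophage table, Kupffer cells were 88.3% in control, 91.5% at 2 weeks and 88.8% at 8 weeks. Because the labels Mac and KC split almost fully by library, and 1 library stands for each condition, the labels alone do not separate a change of cell type from a change of state.

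Dividing Kupffer cells (KC prolif) were 4.41% of control cells, 0.108% of infected cells, 3.67% at 2 weeks and 4.43% at 8 weeks. The infected share was 6 cells, and 0 of the 4819 infected cells that the authors kept as macrophages carried that label. Capsular macrophages, which line the liver surface, were 2.32% in control and 0 of 5545 cells in infection; their share was 0.772% at 2 weeks and 1.79% at 8 weeks. Infected livers held larger shares of patrolling monocytes (3.88% against 0.888% in control), classical monocytes (1.37% against 0.544%), T cells (3.55% against 1.12%), erythrocytes (1.95% against 0.115%) and cross-presenting dendritic cells (cDC1, 0.812% against 0.115%). At 8 weeks these shares were 1.05% for patrolling monocytes, 0.894% for classical monocytes, 1.59% for T cells, 0.0389% for erythrocytes and 0.233% for cDC1. Granulocyte-monocyte progenitors (GMP) were 0 of 3491 control cells, which allows up to 0.0859%, and 0.271%, 0.257% and 0.272% of infected, 2-week and 8-week cells. Endothelial cells made up 23.0%, 4.00%, 13.7% and 20.98% of the control, infected, 2-week and 8-week cells. The sort gated on CD45, CD11b and F4/80, so shares of cells other than macrophages also reflect the gate.

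**Figure D1:**
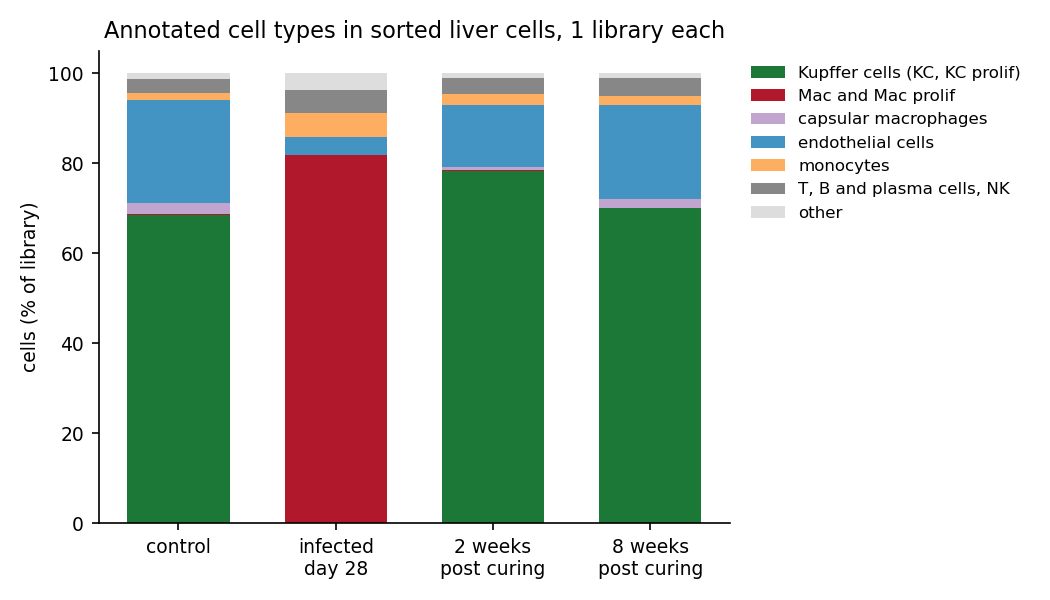
Share of cells (percent of each library) by grouped annotation in control, infected (day 28), 2 weeks and 8 weeks post curing, 1 library each. The Kupffer cell share is near 0 in infection, where Mac cells (78.5%) and their dividing cells fill most of the bar, and Kupffer cells lead again at 2 and 8 weeks.

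The infected macrophages were annotated as 7 subsets. Mac-5 was the most frequent at 24.3% of infected macrophages, followed by Mac-4 at 20.8%, Mac-2 at 14.3%, Mac-6 at 14.2%, Mac-1 at 10.8%, Mac-7 at 3.69% and Mac-3 at 2.18%. Outside the infected library only Mac-1 held any cells, with 11 in control, 3 at 2 weeks and 4 at 8 weeks. The authors' first score for lipid-associated macrophages (LAM, a state that takes up lipid in damaged tissue) had its highest median among the infected subsets in Mac-2, 0.146 (SD 0.106). In Kupffer cells its median was 0.0370 in control (SD 0.0649), 0.0405 at 2 weeks (SD 0.0649) and 0.0371 at 8 weeks (SD 0.0690), which was not tested. The second such score was highest in classical monocytes (medians 0.592 in infection, 0.495 at 2 weeks and 0.413 at 8 weeks). Its median was 0.209 in Mac-2 and -0.0580, -0.0417 and -0.0522 in control, 2-week and 8-week Kupffer cells. By their names, the scores set LAM against macrophages called Mac1 (first) and Mac2 (second), whose definition is not recorded. A high value may therefore mark cells unlike that reference and need not mark LAM.

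The next comparison asks how many Kupffer cells carried the YFP label before and after infection. A YFP count was found in 10.6% of control Kupffer cells (9.31 to 11.9), in 35.0% at 2 weeks post curing (33.0 to 36.9) and in 34.2% at 8 weeks (32.6 to 35.8). Dividing Kupffer cells showed the same order, with 16.9% in control (11.3 to 23.8), 46.5% at 2 weeks (37.1 to 56.1) and 43.0% at 8 weeks (36.5 to 49.7). At day 28, 66.0% of Mac cells carried a YFP count (64.6 to 67.4). Among monocytes, T and B cells together, the share was 39.1% in control (30.9 to 47.8), 48.5% in infection (44.3 to 52.8), 35.3% at 2 weeks (28.2 to 42.9) and 33.8% at 8 weeks (28.3 to 39.7).

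Endothelial cells, which do not descend from Flt3-expressing progenitors, give the background: 0.748% in control, 4.05% in infection, 1.87% at 2 weeks and 1.94% at 8 weeks. Capsular macrophages went the other way from Kupffer cells, with a YFP count in 40.7% of 81 control cells and 31.5% of 92 cells at 8 weeks, intervals that overlap (29.9 to 52.2 and 22.2 to 42.0). The tables hold no total RNA count per cell, so the shares could not be set at equal depth. Asking for 2 or more counts lowered the Kupffer cell shares to 7.25%, 26.2% and 23.3%.

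**Figure D2:**
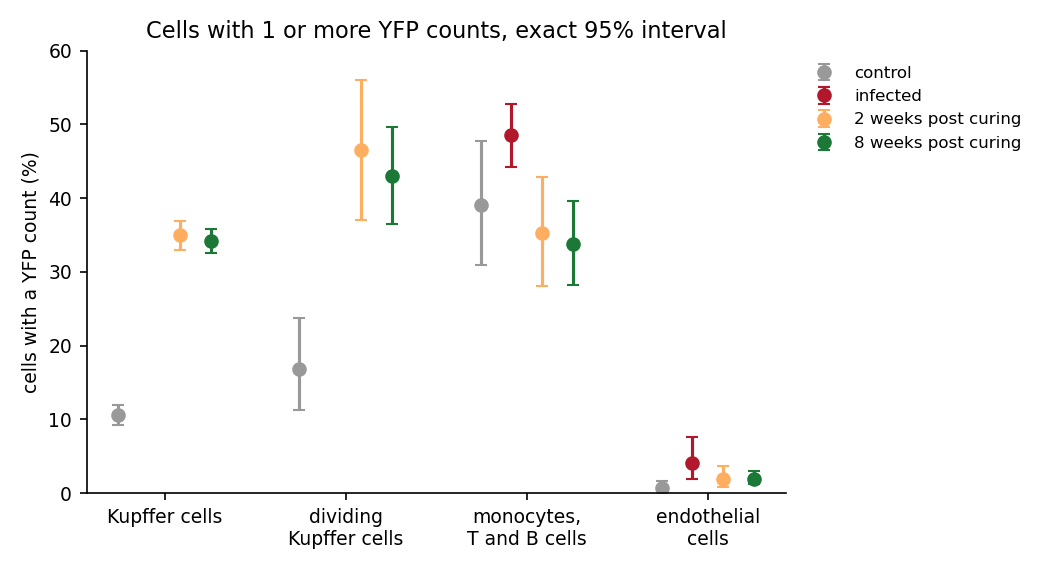
Percent of cells with 1 or more YFP counts in Kupffer cells, dividing Kupffer cells, pooled monocytes, T and B cells, and endothelial cells, by library; bars are exact 95% intervals. Kupffer cells stand at 10.6% in control and at 35.0% and 34.2% after cure, while endothelial cells stay at 4.05% or less; the 6 dividing Kupffer cells of the infected library are not drawn.

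Open chromatin in whole-liver nuclei was compared 8 weeks post curing against control, to ask what remains in Kupffer cells and their neighbours. The control library gave 5560 nuclei with a median of 8220 fragments and the 8-week library 4265 nuclei with a median of 8915, of which 18.0% and 16.3% scored as doublets were left out. Kupffer cell-like nuclei were 7.68% (6.92 to 8.49) of control and 9.41% (8.47 to 10.4) of 8-week nuclei, and hepatocyte-like nuclei 67.9% and 52.5%. Sinusoidal endothelial cell-like nuclei were 10.4% and 15.6%, stellate cell-like nuclei 4.82% and 7.56%, T cell-like nuclei 2.15% and 3.39%, and B cell-like nuclei 1.86% and 3.70%. Neutrophil-like nuclei were 0.592% (0.391 to 0.860) and 2.46% (1.98 to 3.03).

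With hepatocyte-like and unnamed nuclei out of the denominator, neutrophil-like nuclei were still 2.15% of control (1.42 to 3.11) and 5.85% of 8-week nuclei (4.72 to 7.16). On that scale Kupffer cell-like nuclei were 27.9% and 22.3%, and endothelial-like nuclei 37.9% and 37.0%. The direction for Kupffer cells thus turned with the denominator. At a minimum of 5000 fragments the shares of all nuclei were 3.85% and 7.09% for Kupffer cell-like, 3.21% and 8.08% for endothelial-like and 0.176% and 0.993% for neutrophil-like nuclei. A cluster of 31 control and 55 8-week nuclei with macrophage and dendritic cell genes stayed unnamed by a rule set after the data were seen.

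In Kupffer cell-like nuclei (350 control, 336 at 8 weeks, with a median of 3630 and 4758 fragments), genes of the Kupffer cell identity list were more accessible after cure, with a median log2 ratio of 0.19 and 13 of 18 members higher. The list stood at percentile 99.8 of random lists matched on count. Marco, a scavenger receptor for bacteria, was 2.06-fold higher (1.26 to 3.47), the lectin gene Fcna 1.58-fold (1.22 to 2.07) and the complement receptor gene Vsig4 1.39-fold (1.06 to 1.83). Cd163, the haemoglobin-haptoglobin scavenger receptor, went the other way at 0.467-fold (0.332 to 0.651).

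Genes of the monocyte and recruited macrophage list were also more accessible (median 0.27, percentile 99.3, 6 of 8 members higher). Ccr2, the chemokine receptor that brings monocytes into tissue, stood at 1.67-fold (0.9748 to 2.92) and Plac8 at 1.27-fold (1.02 to 1.60). The lipid-associated macrophage list had a median of 0.35 (percentile 99.9, 7 of 8 higher). Lpl, lipoprotein lipase, was 1.83-fold higher (1.15 to 2.97), Lgals3 1.38-fold (1.02 to 1.88), and Trem2, a lipid-sensing receptor gene, stood at 1.62-fold (0.902 to 2.98). The interferon-gamma response list had a median of 0.16 (percentile 98.7, 11 of 18 higher), with the transcription factor gene Irf1 at 1.34-fold (1.06 to 1.68), Gbp5 at 1.83-fold (1.07 to 3.23) and Gbp2 at 0.631-fold (0.409 to 0.968).

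The other lists did not stand apart from random lists in Kupffer cell-like nuclei. Their medians were 0.12 for scavenger and phagocytic receptors (percentile 96.6), 0.14 for inflammatory cytokines and NF-kB (96.1), 0.17 for the type I interferon response (94.9), 0.14 for lipid handling (94.7), 0.11 for MHC class II (85.3), 0.06 for MHC class I and antigen processing (73.3), 0.01 for iron handling (47.7), 0.03 for endothelial-like Kupffer cell genes (51.0), -0.10 for the hepatocyte acute phase (41.1) and 0.10 for sinusoidal endothelial genes (77.4). Single members, picked for the interval bound farthest from 1, still had intervals off 1. Clec7a, the beta-glucan receptor, stood at 1.70-fold (1.13 to 2.60) and the iron and manganese transporter gene Slc11a1 at 1.35-fold (1.10 to 1.66). H2-Ab1 stood at 1.39-fold (1.05 to 1.86), and Il1b, which encodes interleukin-1 beta, at 0.576-fold (0.397 to 0.829). In the simulated counts at a fold of 1.5, 4.17% of unchanged genes also had an interval off 1, so members picked this way need not differ.

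The median log2 ratio of all 12756 genes was -0.01. Each of the 4 calls ended in some setting: with each nucleus thinned to 2000 fragments only the monocyte and recruited macrophage list (percentile 97.6) stood above random lists, and with doublets kept only the lipid-associated macrophage and interferon-gamma lists. Markers of other classes went both ways in these nuclei. Medians were -0.51 for hepatocyte (percentile 0.405), -0.44 for stellate cell (1.25), 0.40 for monocyte or other macrophage (99.5) and 0.28 for endothelial markers (97.4). Signal of other cells may thus have differed between the libraries, and its part in the list medians was not tested. All 7 monocyte or other macrophage markers, 4 of them measured, are also in the monocyte and recruited macrophage list. Their height is therefore not separate evidence of other cells. All 8 markers that named the class, Csf1r and Clec4f among them, are also in the identity list, whose height is therefore not independent of how the class was named.

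**Figure D3:**
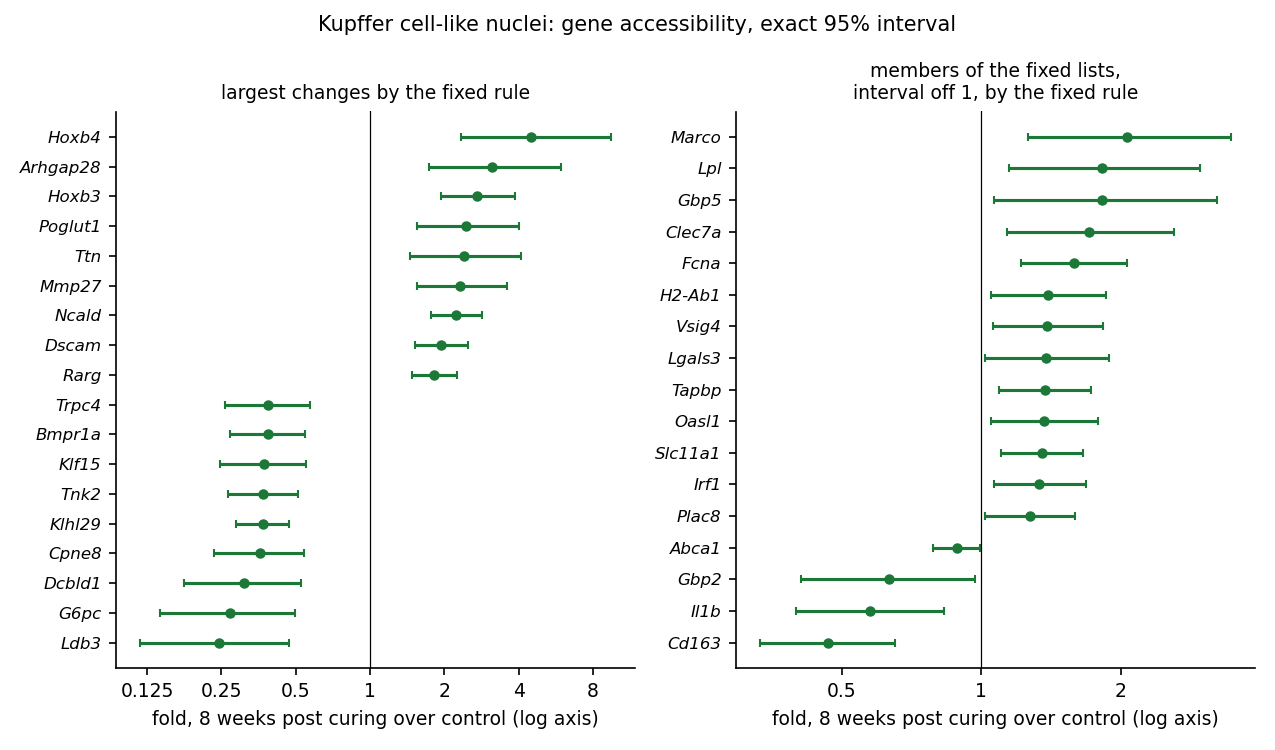
Fold of fragments in gene windows, 8 weeks post curing over control, in Kupffer cell-like nuclei (log axis), with exact 95% intervals. Left, genes from the 10 highest and 10 lowest, led by Hoxb4 at 4.49-fold; right, list members among those whose interval excludes 1, from Cd163 at 0.467-fold to Marco at 2.06-fold.

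Among single genes in Kupffer cell-like nuclei, the homeobox genes Hoxb4 and Hoxb3 were among the highest, at 4.49-fold (2.34 to 9.50) and 2.72-fold (1.94 to 3.88). They encode transcription factors that pattern the embryo and act in blood progenitors. The highest also held Ncald at 2.23-fold, Arhgap28 at 3.13-fold, Poglut1 at 2.46-fold, Mmp27 at 2.32-fold, Dscam at 1.94-fold, the retinoic acid receptor gene Rarg at 1.82-fold and Ttn at 2.40-fold. Among the lowest were Klhl29 at 0.367-fold (0.287 to 0.468), Ldb3 at 0.244-fold, G6pc at 0.272-fold, Tnk2 at 0.370-fold, Dcbld1 at 0.310-fold, Cpne8 at 0.358-fold, Bmpr1a at 0.387-fold, Klf15 at 0.372-fold and Trpc4 at 0.387-fold. G6pc is a liver parenchymal gene of glucose metabolism, and hepatocyte markers were lower as a group in the same nuclei.

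The windows of Hoxb3 and Hoxb4 overlap, so each fragment was counted once over the stretch from Hoxb9 to Hoxb1, called the Hoxb cluster here (chromosome 11, 96269330 to 96370254, mm10). This region held 73 fragments in control and 252 at 8 weeks, or 43.7 and 128 per 1000000 fragments, a 2.94-fold difference (2.26 to 3.87). The share of Kupffer cell-like nuclei with a Hoxb fragment was 15.7% in control (12.1 to 19.96) and 44.9% at 8 weeks (39.5 to 50.4); with each nucleus thinned to 2000 fragments it was 9.14% (6.34 to 12.7) and 19.9% (15.8 to 24.6). In the other classes the Hoxb fold was 0.978 (0.876 to 1.09) in endothelial-like, 1.17 (0.973 to 1.401) in stellate-like, 1.16 (0.693 to 1.98) in T cell-like, 1.13 (0.539 to 2.49) in B cell-like and 0.840 (0.751 to 0.939) in hepatocyte-like nuclei, with 2 and 13 fragments in neutrophil-like nuclei.

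**Figure D4:**
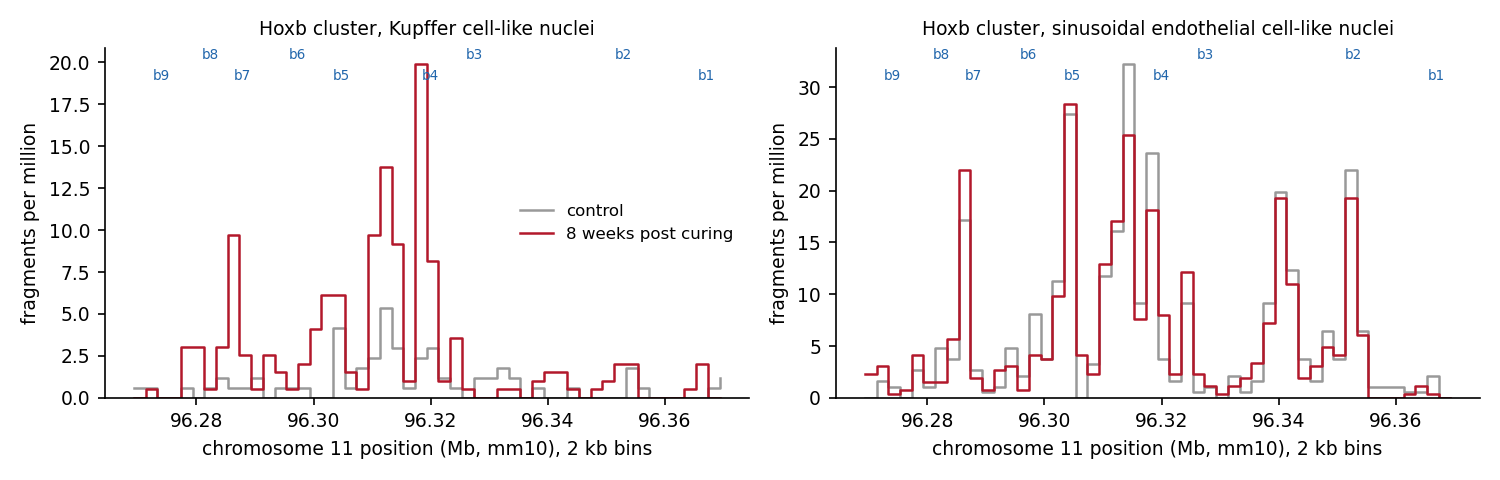
Fragments per 1000000 in 2 kb bins over the Hoxb cluster (chromosome 11) in Kupffer cell-like (left) and endothelial-like (right) nuclei, control in grey and 8 weeks post curing in red, with gene positions marked and vertical scales that differ. Kupffer cell-like nuclei show 43.7 and 128 fragments per 1000000 over Hoxb, endothelial-like nuclei 302 and 295.

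Only 500 bp windows with 20 or more fragments per 1000000 were compared in Kupffer cell-like nuclei. Of these 4257 windows 94.4% lay within a factor of 1.5, against 96.5% if both libraries were at 1 level. Above that factor lay 3.76% against 2.09%, and below it 1.81% against 1.46%. When scaled to the median ratio over windows, 2.77% lay above and 2.58% below, so the tilt towards higher windows depended on the scaling. The highest windows lay in Csf2ra, the receptor gene for GM-CSF (chromosome 19, 61227001 to 61227500; 2.10-fold, 1.38 to 3.28), Hnrnph1 (chromosome 11, 50377501 to 50378000; 2.12-fold), Grb2 (chromosome 11, 115708501 to 115709000; 2.18-fold), a gene-poor stretch (chromosome 2, 98667001 to 98667500; 1.58-fold) and the shared window of Setd3 and Ccnk (chromosome 12, 108179001 to 108179500; 2.13-fold). The lowest lay beside Narf (chromosome 11, 121236501 to 121237000; 0.449-fold, 0.276 to 0.717), at Xrcc4 and Tmem167 (chromosome 13, 90089501 to 90090000; 0.498-fold), in Rwdd1 (chromosome 10, 34019501 to 34020000; 0.517-fold), at Pus7l and Irak4 (chromosome 15, 94543501 to 94544000; 0.523-fold) and in Kdsr (chromosome 1, 106759501 to 106760000; 0.504-fold). A minimum of 40 fragments per 1000000 left 550 windows, 98.0% of them within the same factor. The chromosome 2 window lies in a repeat region known for spurious signal, and no such regions were left out.

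In sinusoidal endothelial cell-like nuclei (476 control, 557 at 8 weeks), antigen presentation genes were more accessible after cure. The MHC class II list had a median of 0.86 (percentile 100, 5 of 5 members higher), with H2-Ab1 at 2.18-fold (1.33 to 3.71) and Ciita, the master regulator of the class, at 1.94-fold. The interferon-gamma response had 0.33 (percentile 100, 13 of 17 higher), the inflammatory list 0.24 (99.1, 6 of 8) and MHC class I 0.22 (99.3, 8 of 9), with Gbp7 at 1.86-fold, Cxcl1 at 1.78-fold, Psmb8 at 1.76-fold and H2-K1 at 1.55-fold. The scavenger receptor list was lower, with a median of -0.20 (percentile 0.28) and 6 of 9 members lower, among them Scarb1 at 0.789-fold, Fcgr2b at 0.801-fold and Mrc1 at 0.817-fold; in nuclei with 5000 or more fragments its median was 0.03.

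Of the 4 higher lists in endothelial-like nuclei, only the interferon-gamma list stayed above random lists with promoter windows, only the inflammatory list when thinned and only MHC class I at 5000 fragments. The MHC class II list had too few measured members in each of these settings, so its call was not tested there. In these nuclei B cell markers had a median of 0.20 (percentile 94.2, 4 of 4 higher) and dendritic cell markers -0.12 (24.3). The endothelial markers that named the class were at -0.10 (5.24). None of these stood apart from random lists, and the part of other cells in the list medians was not tested.

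The highest single genes in these nuclei were Birc3, an inhibitor of apoptosis induced by NF-kB, at 2.27-fold (1.69 to 3.10), Plch1 at 2.87-fold, Bmpr1b at 2.59-fold, Tifa at 2.21-fold and Cyba, an NADPH oxidase subunit gene, at 2.30-fold. The lowest were Rbm43 at 0.297-fold, Agap2 at 0.345-fold, Gm10044 at 0.334-fold, E2f6 at 0.413-fold and Slc6a9 at 0.448-fold. The remaining lists gave medians from -0.17 for Kupffer cell identity (percentile 5.28) to 0.07 for the type I interferon response (82.4).

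In hepatocyte-like nuclei (3098 control, 1873 at 8 weeks), all 15 acute phase genes, which encode plasma proteins that the liver makes in inflammation, were more accessible after cure (median 0.65, percentile 100). Saa2 stood at 2.77-fold (2.38 to 3.22), Saa1 at 2.47-fold (2.25 to 2.72), haptoglobin (Hp) at 2.55-fold (2.40 to 2.70) and complement C3 at 2.25-fold (2.15 to 2.36). The genes furthest up were Steap4 at 3.50-fold, haemopexin (Hpx) at 3.22-fold, Tnfsf14 at 3.32-fold, Igfbp1 at 2.91-fold and Hp. The furthest down were Krtap16-1 at 0.193-fold, Prelid2 at 0.422-fold, Cldn18 at 0.405-fold, Klk9 at 0.285-fold and Dkk4 at 0.420-fold.

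Interferon-gamma response genes were more accessible in hepatocyte-like nuclei as well (median 0.26, percentile 100, 16 of 20 higher; Cxcl10 at 1.71-fold), as were MHC class II (0.21, percentile 99.9, 6 of 7), MHC class I (0.20, 99.5, 9 of 9), iron handling (0.20, 99.6, 9 of 10; Hmox1 at 1.497-fold) and the type I interferon response (0.12, 99.8, 7 of 10). The share of fragments at promoters was 23.8% in control and 26.3% at 8 weeks. When thinned, the MHC class I, iron handling and type I interferon lists no longer stood above random lists, while the acute phase (0.70), interferon-gamma (0.36) and MHC class II (0.36) lists did. Tnfaip3 at 2.21-fold and Cxcl1 at 2.15-fold were higher although the inflammatory list as a whole was at -0.05 (percentile 90.4). At resolution 1 each of the 8 hepatocyte clusters held 90% or more of its nuclei from 1 library, unlike the clusters of the other classes. Clusters 0, 2, 5 and 13 were mostly from control, and 3, 6, 9 and 12 mostly from 8 weeks. At resolution 2 a hepatocyte cluster of 535 nuclei held 223 control and 312 8-week nuclei.

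**Figure D5:**
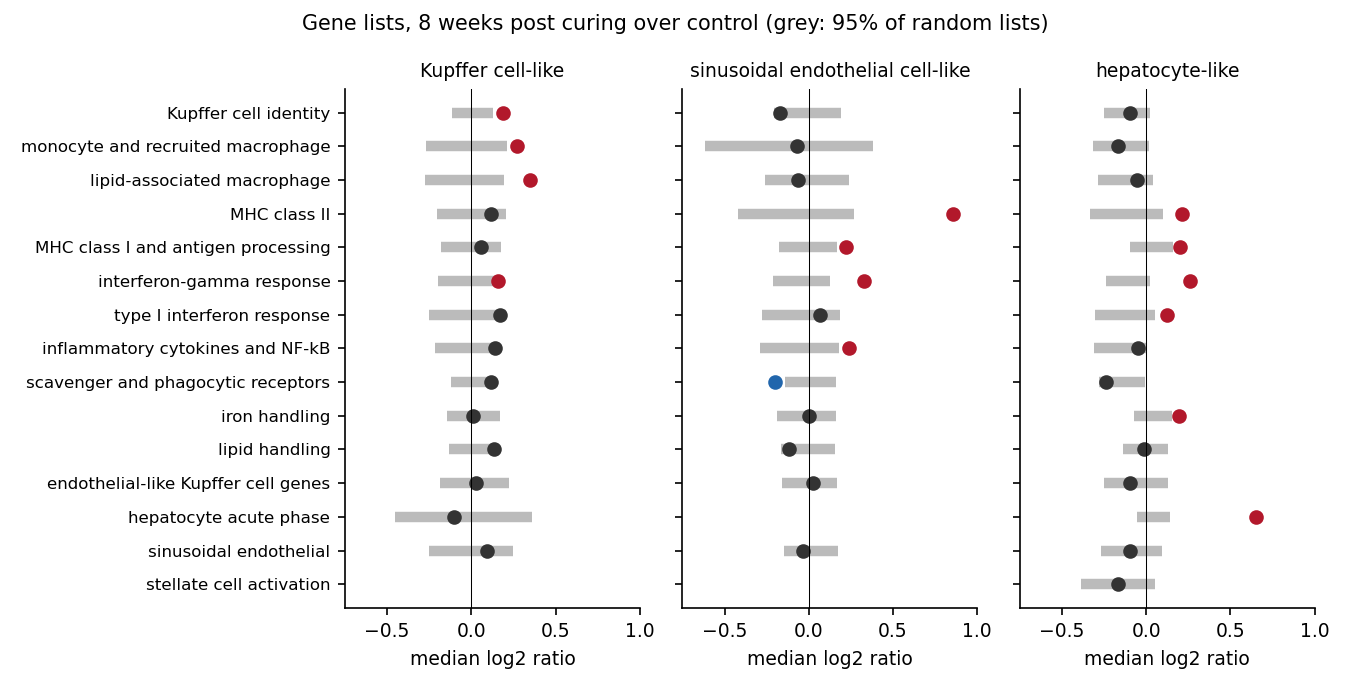
Median log2 ratio of each fixed gene list, 8 weeks post curing over control, in Kupffer cell-like, endothelial-like and hepatocyte-like nuclei; grey bars span 95% of random lists, and red and blue points lie above and below them. The acute phase list reaches 0.65 in hepatocyte-like nuclei and MHC class II 0.86 in endothelial-like nuclei.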

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

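The comparison of list medians between classes of nuclei was chosen after the medians were seen, and no difference between classes was tested. A list was picked where it stood apart from random lists in one class and near the opposite end in another. The Kupffer cell identity list was higher by 0.36 (log2) in Kupffer cell-like than in endothelial-like nuclei, at percentiles 99.8 and 5.28, from 18 and 9 measured members. The scavenger and phagocytic receptor list differed by -0.32 between endothelial-like and Kupffer cell-like nuclei, at percentiles 0.28 and 96.6 and from 9 and 20 measured members; Marco, Vsig4, Clec4f, Cd163 and Timd4 are in both lists. The MHC class I list was higher than in B cell-like nuclei by 0.33 in hepatocyte-like, 0.34 in endothelial-like and 0.48 in T cell-like nuclei, with B cell-like nuclei at percentile 9.41 from 85 control and 132 8-week nuclei and with 7 measured members against 9. These differences are thus partly between different sets of genes.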

How the results depend on the processing

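Added after seeing the data were the 2-count YFP minimum, the restriction to cells below the median doublet score or mitochondrial percent, and lists matched also on gene length. Of 1100 checks on single genes 984 stayed within the counting interval, 106 moved and 10 reversed. Of 502 checks on list medians 456 kept their place above, within or below the range of random lists. These include lists within the range in both settings, so 456 is not a count of calls that held. A call was lost in 31 checks, gained in 13 and reversed in 2. Kupffer cell shares were 83.2%, 86.5% and 83.0% (control, 2 and 8 weeks) without endothelial cells. With all cells in place of macrophages as the denominator, Kupffer cell shares were 64.1%, 74.7% and 65.6%. YFP shares of Kupffer cells in the same order were 7.25%, 26.2% and 23.3% at 2 or more counts, 13.9%, 46.8% and 44.1% at low doublet scores, and 12.7%, 44.7% and 39.0% at a low mitochondrial percent. At 5000 or more fragments the 8-week median was 14315, Kupffer cell-like nuclei were 3.85% and 7.09%, and the endothelial Hoxb fold was 1.16; with doublets kept the control Kupffer share was 6.74%.

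Lists above random lists in Kupffer cell-like nuclei numbered 1 when thinned and 2 with doublets kept. In endothelial-like nuclei 1 stood above with promoter windows, when thinned and at 5000 fragments, and 0 below with promoter windows and at 5000. In stellate-like nuclei 1 stood above with promoter windows, 0 when thinned and 5 with doublets kept, with 1 below with doublets kept and at a count minimum of 20. In T cell-like nuclei 0 stood above when thinned, at 5000 fragments, with doublets kept and with length matching. In B cell-like nuclei 0 stood above with promoter windows (1 below), when thinned, at 5000 fragments and at a count minimum of 20. Windows numbered 550 at 40 per 1000000.

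Reversed log2 ratios were, in hepatocyte-like nuclei, -0.00851 for the type I interferon list when scaled to promoters (which lowers all genes alike and leaves its place among random lists), 0.0147 for Stab1 when thinned, -0.35 for Vwf and 0.0348 for Clec4g with promoter windows, and 0.30 for Clec4g when thinned. In endothelial-like nuclei they were 0.0326 for the scavenger list, 0.10 for Fcgr2b and 0.0262 for Mrc1 at 5000 fragments, 0.0251 for Fcgr2b and 0.71 for Stab2 with promoter windows, and -0.0221 for Tap1 when thinned; in Kupffer cell-like nuclei 0.0330 for Abca1 when thinned. Of 80 shares of nuclei 27 moved. At 5000 fragments (control and 8 weeks) they were 85.0% and 69.0% hepatocyte-like, 3.21% and 8.08% endothelial-like, 1.73% and 4.83% stellate-like, 0.706% and 1.63% T cell-like, 0.529% and 1.44% B cell-like, 0.176% and 0.993% neutrophil-like, and 6.91% unnamed at 8 weeks. With doublets kept they were 61.3% and 46.3% hepatocyte-like, 8.92% and 13.7% endothelial-like, and 14.5% and 15.01% unnamed; at resolution 0.5, 2.52% and 5.10% B cell-like, 3.14% and 8.32% unnamed, and 47.5% hepatocyte-like at 8 weeks. For all of these the cause was not tested. The Hoxb fold in Kupffer cell-like nuclei ran from 2.94 to 3.61 over its alternatives. Not run, for want of total RNA counts or a genome, were the alternatives on cells with 1000 or more RNA molecules, on the library medians, and on motifs. No paired analysis was possible because the groups compared have 1 library each; the bulk libraries that share replicate numbers were not analysed here.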

Other observations

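Several tests below were chosen only after the result they bear on was seen. These were the tests on endothelial YFP, on pooled blood cells, on YFP counts per cell and on dividing Kupffer cells. The tests on Hoxb in endothelial-like nuclei, on promoter windows and on the state of the mice were also chosen then. Those on endothelial markers, on nuclei with a Hoxb fragment and on pairs of hepatocyte clusters were set before their own values were seen. The Hoxb cluster itself was chosen after the values of its genes were seen, and the pairs rest on clusters made from these data. The tests on pooled blood cells, on YFP counts per cell and on dividing Kupffer cells were set to open after their values were seen. So were those on nuclei with a Hoxb fragment and on cluster pairs.

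The infected macrophage subsets differed in YFP. A YFP count was found in 64.6% of Mac-1, 68.7% of Mac-2, 60% of Mac-3, 73.7% of Mac-4, 76.0% of Mac-5, 46.1% of Mac-6 and 30.3% of Mac-7 cells. The median mitochondrial percent was higher in Mac-6 (9.09) and Mac-7 (7.03) than in Mac-5 (5.90), though Mac-3 had 7.08, so RNA quality is not separated from the difference. In stellate cell-like nuclei (220 control, 270 at 8 weeks), the interferon-gamma response (median 0.39, percentile 100, 12 of 13 members higher), inflammatory (0.59, percentile 100, 4 of 4) and acute phase (0.55, percentile 99.6, 3 of 3) lists were more accessible after cure, while the stellate cell activation list, which holds collagen and contractile genes, was at -0.11 (percentile 31.5). Of these, 0 lists stood above random lists when nuclei were thinned and 1, the inflammatory list, with promoter windows. Markers of other classes differed in the same nuclei, with medians of -0.88 for hepatocyte, -0.57 for endothelial and 0.56 for dendritic cell markers. B cell-like nuclei had 4 of 4 measured interferon-gamma genes higher (median 0.84, percentile 100), and T cell-like nuclei 8 of 9 MHC class I genes (0.35, percentile 98.3). The B cell call was lost, or its list not measurable, with promoter windows, when thinned, at 5000 fragments and at a count minimum of 20, and the T cell call when thinned, at 5000 fragments, with doublets kept and with lists matched on gene length.

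In hepatocyte-like nuclei 26 genes of the clock, of liver zonation and of metabolism were looked at after the results were seen, and they gave no single picture. The metallothionein genes Mt1 and Mt2, which bind zinc and respond to stress, stood at 2.59-fold and 2.35-fold, and the fasting hormone gene Fgf21 at 1.48-fold. The urea cycle genes Ass1 and Cps1 stood at 0.562-fold and 0.741-fold, and the pericentral genes Cyp1a2 and Lgr5 at 0.712-fold and 0.713-fold, but the pericentral gene Glul at 1.17-fold. Of the glucose genes raised by fasting, Pck1 stood at 1.13-fold and G6pc at 0.811-fold, and Tat, which glucocorticoids raise, at 0.699-fold. The clock genes Per1 and Nr1d1 stood at 1.26-fold and 1.25-fold and Per2 at 1.012-fold.

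The YFP share of Kupffer cells was 10.6% in control and 34.2% at 8 weeks, and entry of labelled marrow-derived cells into the Kupffer cell pool is a candidate explanation. Free YFP molecules would label endothelial cells too, but 1.94% of them had a count at 8 weeks. More counts per labelled cell could raise the share of positive Kupffer cells with 3 or more counts. That share was 46.2% in control (39.7 to 52.8), 54.2% at 2 weeks (50.7 to 57.7) and 46.8% at 8 weeks (43.9 to 49.8). The 2-week share thus lay above the control's interval, and the 8-week share within it. Cells newly found with 1 or 2 counts would hold the share down, so more counts per cell stays open. Stronger labelling of blood cells in the cured mice stays open. Monocytes, T and B cells together had 33.8% (28.3 to 39.7) at 8 weeks against 39.1% (30.9 to 47.8) in control, so no rise was seen. From control to 8 weeks T cells (48.7% to 29.3%) and patrolling monocytes (45.2% to 33.3%) were lower. Classical monocytes (47.4% of 19 to 52.2% of 46) and B cells (24.5% of 49 to 29.3% of 99) were higher. The intervals overlapped in each of these types. Entry and a difference between groups of mice in the label of Kupffer cells before infection cannot be told apart with 1 library per condition, and both would give the 43.0% against 16.9% seen in dividing Kupffer cells.

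The Hoxb cluster was more accessible in Kupffer cell-like nuclei after cure, and a share of Kupffer cells of another origin, marrow progenitors with active Hox genes among them, is a candidate explanation. Endothelial nuclei mixed into the class would need 33.7% of its fragments, and with it 939 fragments per 1000000 over 8 endothelial markers, where 337 (311 to 363) were found against 303 in control. A difference between the libraries as a whole would show in endothelial-like nuclei, where the Hoxb fold was 0.978. Whether Hoxb goes with the other named genes that were higher stays open: within the 8-week library their ratio between nuclei with and without a Hoxb fragment was 1.10 (0.971 to 1.24), and a nucleus without a fragment may still be open there. The bound set beforehand, an interval that holds 1, was met and would have excluded it.

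The rise of acute phase gene accessibility in hepatocyte-like nuclei may reflect a lasting response to the infection, or the state of the mice at collection. A shift of fragments towards promoters would raise all promoters alike, but in promoter windows alone the list median was 0.52, above the upper end of random lists (0.20). For genes without a clear promoter end these windows can include the other gene end. Another mix of hepatocyte states stays open. The lowest of 16 pairs of a control and a cured cluster had a median of 0.17 and the highest 1.199. At resolution 1, however, each cluster is almost all from 1 library and some cured clusters lead with acute phase genes. No pair there holds like nuclei, so the bound set beforehand, a median above 0, could not speak against another mix. At resolution 2 a hepatocyte cluster held 223 control and 312 8-week nuclei, but the list was not compared within it. The infection history and the state of the mice at collection cannot be told apart with 1 cured library, in which Igfbp1, a gene raised by fasting and stress, was 2.91-fold higher.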
